A study of Mus musculus with 4 samples.

How the data were processed

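RNA of multimer-binding cells (CTRL) and of a population labelled residual was sequenced in the B16 and CT-26 tumour models, 1 library per group and 4 in all. Per the labels, both are CD8+ lymphocytes isolated from mouse peripheral blood mononuclear cells (PBMC). Per the labels' protocols, libraries were made with the Takara SMART-Seq v4 ultra-low input kit. The submitters' processing notes name STAR 2.7.3a, HTSeq 0.11.2, DESeq2 and the genome build mm10, without saying what each was used for. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

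The deposited data were a table per model with 53801 Ensembl genes. Each table gives raw read counts per gene and library as whole numbers, which the authors deposited beside normalized values. The normalized read counts, a signal per gene per the file headers, equal the deposited raw counts divided by a size factor of 0.766 and 1.31 for the B16 residual and CTRL libraries, and 0.770 and 1.30 for CT-26, which match a median-of-ratios calculation on the deposited counts. The log2 fold in the authors' deposited table is CTRL over residual, and for some genes, such as Cd8b1 in B16, it is far smaller in size than the ratio of the normalized counts. The p-value in the authors' deposited table is not adjusted, and no adjusted p from that table is used here. The models were normalized separately, so normalized levels were compared only within a model.

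With 1 library per group no test was run within a model, and the authors' p-values are given only as theirs. The main value is log2 of the ratio of deposited normalized counts with a pseudocount of 1. The plan named the authors' fold as the starting choice for gene lists and named genes and the ratio of the libraries as the main comparison; the ratio is used throughout and the authors' fold is an alternative. A gene passed the rule of size when its log2 ratio was at least 1 in size and its higher library had at least 10 CPM, computed from the raw counts and the library total. That level equals 391, 372, 508 and 749 reads in the B16 residual, B16 CTRL, CT-26 residual and CT-26 CTRL libraries. Exact 95% intervals of ratios and Wilson intervals of shares cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. Where a library had 0 reads, a fold was computed against a floor of 3 reads per library and given as a lower bound.

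Before the data were examined, 29 gene lists were fixed, 13 of them markers of other cell types, with 740 memberships, of which 6 matched no gene. Each list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean level, as a description of these libraries. A list was read as standing apart below percentile 2.5 or above 97.5. Some genes stand in more than 1 list, such as Gzma among cytotoxic and NK cell genes, and Ccr9 among naive and dendritic cell genes. Where a symbol had several Ensembl identifiers, the identifier with most reads was used. Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and falls per model among called genes above the median of mean level, leaving out predicted genes, pseudogenes and receptor segments. It also took up to 4 members per list with a mean of at least 10 normalized counts, 11 fixed genes, the 10 genes with the largest smaller ratio in a shared direction under the same exclusions, and up to 5 TCR segments per model. Some genes that this rule takes are not reported here. Lyz2, Cd79a, Ms4a1 and several genes of the closing section were chosen after their values were seen. Globin, Klra, immunoglobulin and TCR segment genes have near-identical copies, so reads may be split among them and their single values are uncertain.

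Gene positions came from GENCODE M21 on the same build and covered 99.8% of the identifiers. Alternatives were other scalings, pseudocounts of 0.1 and 5, other size and level limits, sets of genes left out and the authors' fold. A fit over both models, added after seeing the data, used the raw counts of the 4 libraries with population and model as terms. Its first setting was edgeR's quasi-likelihood test with TMM factors, filterByExpr and Benjamini-Hochberg adjustment, and DESeq2 was among the others. Scripts were tested on simulated data, with 200 of 53801 genes changed in counts drawn at the depth of each model. At 2-fold, the size of its own limit, the rule recovered 51% of changed genes in B16 and 50.5% in CT-26 with counting noise alone. With a dispersion of 0.05 it recovered 49.5% and 52.5%. At 4-fold, the rule recovered 100% of changed genes in both models with counting noise alone, and 97.5% in B16 and 98.5% in CT-26 with a dispersion of 0.05. At that dispersion it also called 273 unchanged B16 genes of 8203 and 290 unchanged CT-26 genes of 8930. For the fit over both models, simulated with 200 changed genes at the same dispersion, edgeR recovered 22.5% of genes changed 2-fold and 98.5% of those changed 4-fold, and called 4 of 20293 and 8 of 20608 unchanged genes. The common dispersion that the fit estimated from the real counts was 0.36, above the simulated one, and it takes in differences between models. At a higher dispersion more unchanged genes would pass the rule, and neither the rule nor the fit was simulated there. The simulated rates therefore do not give the share of false calls among the real calls, which may be much larger. In the simulation of the rule, both libraries of a model shared the same mean profile but for the changed genes. Their scaling was known, so normalization was not tested. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.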

Results

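RNA was sequenced from blood cells in the B16 and CT-26 tumour models. B16 is a mouse melanoma line and CT-26 a mouse colon carcinoma line. Per the labels, CD8+ cells that bound MHC multimers, which are labelled peptide and MHC complexes that bind T cells by their receptor, gave the circulating tumor-reactive lymphocytes (CTRL), and a residual population was labelled CD8+ as well. The labels do not say whether the residual was the unbound CD8+ cells or all that was left of the blood cells, which changes what each ratio compares. The design asks how the multimer-binding cells differ from the residual. Each of the 4 groups held 1 library, so no difference within a model has a replicate check or a test, and the contrast is repeated only across the 2 models. The plan of the comparison took the models as different mouse strains as well as different tumours. A difference between models therefore cannot be told apart from a difference of strain. Depth was 39068457 reads in genes for the B16 residual library, 37166063 for B16 CTRL, 50823018 for CT-26 residual and 74879891 for CT-26 CTRL. All log2 ratios are CTRL over residual from normalized read counts, so a positive value means higher in CTRL. A gene was counted as higher or lower when its log2 ratio reached 1 in size and its higher library reached 10 CPM. Intervals given with log2 ratios are 95% exact counting intervals, which cover counting error only.

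The coreceptor genes were read first, since the labels call all 4 populations CD8+. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173 on mm10) rose from 84.9 to 12059 normalized counts between the residual and CTRL libraries of B16, and from 579 to 42367 in CT-26. Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494), the beta chain of the coreceptor, rose from 79.7 to 25827 and from 1630.4 to 91021. Cd3e, a subunit of the T-cell receptor complex, differed far less, with log2 ratios of 2.25 in B16 and 1.90 in CT-26. Per Cd3e read, the B16 library labelled residual held 0.0392 Cd8a reads and its CTRL library 1.17; the CT-26 values were 0.0502 and 0.982. These levels go against the CD8+ label of the residual libraries, and the wording "the library labelled residual" is meant wherever a direction is given.

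**Figure D1:**
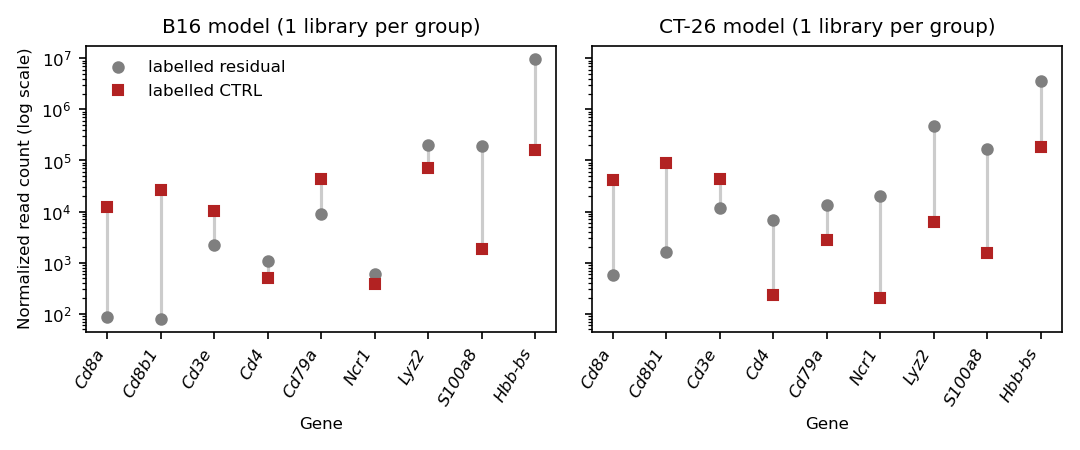
Normalized read counts on a log scale of 9 marker genes in the 4 libraries, 1 point per library, circles for the library labelled residual and squares for CTRL, with B16 on the left and CT-26 on the right. Cd8a and Cd8b1 are higher in CTRL in both models, S100a8 and Hbb-bs are lower, and Cd79a is higher in CTRL in B16 and lower in CT-26.

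In the B16 model the CTRL library was rich in transcripts of T cells and B cells, and the library labelled residual in transcripts of red cells, platelets and neutrophils. The B-cell list held 1540130 reads in B16 CTRL and the T-cell identity list 250354, whereas in CT-26 CTRL they held 116506 and 952120. Read totals of unlike genes do not give shares of cells, but much of the RNA of B16 CTRL may come from B cells. Beside Cd8b1 (log2 8.32, 7.98 to 8.73) and Cd8a (7.13, 6.80 to 7.52), Itgae, the integrin chain of CD103, was higher by 4.81 (4.50 to 5.17). Ngp, Ltf and Camp, proteins of neutrophil granules, had no reads in CTRL and were at least 4916-fold, 1585-fold and 1027-fold lower. Hbb-bs, a beta globin, fell by 5.95 on the log2 scale, with 7602423 reads against 209361.

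Of 9289 B16 genes that reached the level, 2485 were higher in CTRL and 1088 lower, so 69.5% of the calls were higher. Scaled to total reads, 5911 were higher and 597 lower, or 90.8%, since that scaling adds 0.84 to the median log2 ratio. Haemoglobin genes held 42.0% of the reads of the library labelled residual and 1.28% of those of CTRL. At 4-fold, 409 genes were higher and 551 lower.

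The other genes with the largest rises among well expressed genes in B16 were Wdr6 (3.34), Fcmr (3.30), Cr2 (3.27), Gga2 (3.20), Adgrg5 (3.08), Tdrp (2.97) and Usp11 (2.91). Fcmr, an Fc receptor for IgM, and Cr2, complement receptor 2, are known from B cells. Among the largest falls, Ctsf, Rhov and Add2 had no reads in CTRL and were at least 2395-fold, 1971-fold and 1407-fold lower. Rhag of the Rh complex was at -7.51, Cox6b2 at -8.40 and Gstm5 at -8.08.

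Genes of T-cell identity were higher in B16 CTRL, with 15 of 18 members higher and 0 lower and a median log2 ratio of 1.49, above all 10000 random lists matched on level. Lck, the kinase that binds CD8, reached 1.87 and Cd6 1.80. The naive and central memory list had 10 of 20 members higher and 1 lower, a median of 0.94 (percentile 99.8), led by Ccr9 (3.44), Cd27 (2.22) and the lymph node homing receptor Ccr7 (1.96). Tcf7, a transcription factor of naive and memory T cells, was at 1.72. TCR variable segments had a median of 1.15 (above all 10000 random lists; 1.08 with zeros at their bound), with 12 of 113 members higher and 0 lower. Class I antigen presentation had 4 of 12 members higher and 0 lower and a median of 0.85 (percentile 98.7), with Nlrc5 at 1.41 and the peptide transporter gene Tap1 at 1.29. B cells express Ccr7 and class I presentation genes too, and the B-cell list rose further in the same comparison, to a median of 2.05.

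Effector and memory differentiation genes were lower in B16 CTRL, with 2 of 25 members higher and 11 lower and a median of -0.77 (percentile 0.03). Anxa1 was at -3.24, S100a6 at -2.78, Cd44, a receptor raised on antigen-experienced T cells, at -2.49 and Bhlhe40 at -2.47. Myeloid cells also express Anxa1, S100a6 and Cd44, and neutrophil markers fell beside them. TCR activation genes had 2 of 23 members higher and 7 lower and a median of -0.28 (percentile 2.34), with Nr4a3 at -5.64 and Nfkbia at -2.47. Interferon-stimulated genes had 5 of 29 members higher and 9 lower and a median of -0.18 (percentile 0.48), with Rsad2 at -5.52 and Isg15 at -5.50. Myeloid cells express genes of both lists too, and the neutrophil list fell to a median of -5.16 beside them. Cytosolic ribosomal protein genes had 0 of 75 members higher and 9 lower and a median of -0.10 (percentile 1.64). All 4 of these medians turn positive when libraries are scaled to total reads. The mitochondrially encoded list had 0 of 34 members higher and 12 lower and a median of -1.84 (below all 10000 random lists; -1.74 with zeros at their bound), with the ribosomal RNA gene mt-Rnr1 at -5.46.

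Cytotoxic effector genes went both ways in B16, with 4 of 19 members higher and 5 lower and a median of -0.01 (percentile 13.9). Gzmk, a granzyme, had 2 reads against 803 and a ratio of 7.41 (6.02 to 10.93), whereas Tnf was at -5.49 and the chemokine Ccl4 at -4.61. Gzmb, at 0.58, and Ifng, at 0.02 (-0.31 to 0.36), did not pass the rule of size. Pdcd1, which encodes PD-1, had 4 reads against 225 and a ratio of 4.80 (3.67 to 6.93), under the level set for a call. Inhibitory receptor genes had 4 of 20 members higher and 1 lower (median 0.42, percentile 69.5), and chemokine receptor and integrin genes 6 of 19 members higher and 2 lower (median 0.24, percentile 47.8), Cxcr6 reaching 4.14 and Cxcr5 2.69. Proliferation genes had 8 of 28 members higher and 5 lower (median 0.43 but mean -0.04, percentile 67.0), with Mki67, a marker of cycling cells, at -3.52 and Ube2c at -5.47. Glycolysis genes had 0 of 17 members higher and 4 lower (median -0.11, percentile 6.11), with the lactate transporter gene Slc16a3 at -2.61. Oxidative phosphorylation genes had 1 of 23 members higher and 6 lower (median -0.18, percentile 2.90), and heat shock genes 2 of 16 members higher and 4 lower (median 0.05 but mean -0.33, percentile 28.4). Under total scaling the medians of the cytotoxic, glycolysis and oxidative phosphorylation lists, which did not stand apart, turned positive as well. Cells of other types express proliferation, metabolic and mitochondrially encoded genes too, and the neutrophil and erythroid lists fell to -5.16 and -5.27 in the same comparison. The falls of Mki67, Ube2c and Slc16a3 therefore cannot be placed in T cells. Cxcr5 rose where the B-cell list rose to 2.05, while in CT-26, where that list fell to -2.25, its authors' fold was -0.25. The rise of Cxcr5 cannot be placed in T cells either.

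Several lists of markers of other cells moved strongly in B16, while others did not stand apart. B-cell genes had 18 of 20 members higher and 0 lower and a median of 2.05 (above all 10000 random lists), with Fcer2a at 2.90 and Cd79b, a subunit of the B-cell receptor complex, at 2.66. Plasma cell genes had a median of 1.48 but a mean of -0.78 (percentile 99.99), with 5 of 12 members higher and 1 lower, and Igha at -3.62. Neutrophil genes had 0 of 15 members higher and 15 lower (median -5.16, below all 10000 random lists), erythroid genes 0 of 17 members higher and 14 lower (median -5.27, below all 10000 random lists) and platelet genes 0 of 14 members higher and 12 lower (median -3.80, below all 10000 random lists), with Gp1bb at -6.18. NK cell genes had 1 of 18 members higher and 11 lower (median -1.46, below all 10000 random lists), monocyte and macrophage genes 1 of 21 members higher and 9 lower (median -0.94, percentile 0.08) with Cd14 at -4.73, and dendritic cell genes 1 of 12 members higher and 0 lower (median -1.34, percentile 0.26). Cd4, the coreceptor of helper T cells, fell by 1.11 on the log2 scale, while its list had 0 of 11 members higher and 1 lower (median 0.36, percentile 47.1). Gamma delta T cell genes had 2 of 9 members higher and 1 lower (median 0.92, percentile 95.7). Melanoma genes had 0 of 11 members higher and 0 lower (median -2.99, percentile 0.195; -2.77 with zeros at their bound), on 747 and 759 reads in all. Epithelial genes had 0 of 12 members higher and 1 lower (median -3.27, percentile 0.02; -2.51 with zeros at their bound) and endothelial and stromal genes 1 of 10 members higher and 0 lower (median -2.63, percentile 13.1; -1.94 with zeros at their bound). Several members of these 3 lists had no reads in 1 library, and the B16 library labelled residual stood apart in genes of few reads, with 16985 genes of 1 to 9 reads against 5880 to 7188 in the other libraries.

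In the CT-26 model the CTRL library held more RNA of CD8+ and naive T-cell genes, and less of myeloid, NK, B-cell and plasma cell genes, than the library labelled residual. Cd8a was higher by 6.19 (6.06 to 6.33) and Cd8b1 by 5.80 (5.72 to 5.88). Lyz2, the lysozyme of myeloid cells, fell by 6.26 on the log2 scale, and Ncr1, a receptor of NK cells, was at -6.62. Ighg2b, an IgG constant region, had 3862 reads against 4 and fell by 10.26 on the log2 scale.

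Of 9514 CT-26 genes at the level, 1381 were higher in CTRL and 1555 lower, so 47.0% of the calls were higher. Scaled to total reads, which adds 0.19 to the median log2 ratio, 1981 were higher and 1386 lower, or 58.8%. Haemoglobin genes held 10.8% and 0.629% of the reads of the library labelled residual and of CTRL. At 4-fold, 208 genes were higher and 974 lower.

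After the coreceptor genes, the largest rises among well expressed CT-26 genes were Ggt1 (4.06), Fgf13 (3.76), Rgs11 (3.42), Tanc1 (3.39), Sidt1 (3.38), Crtam (3.34), Btbd11 (3.33) and Cxcr6 (3.32). Crtam is a surface receptor of activated cytotoxic cells and Cxcr6 a chemokine receptor of T cells. The largest falls after Ighg2b were Dmxl2 (-8.25), Aif1 (-7.73), Cd300c2 (-7.41), Il1r2 (-7.38), Ngp (-7.20), Ptpro (-7.15), Rasgrp4 (-7.09), Camp (-7.08) and Cyp27a1 (-7.07). Aif1 is a calcium-binding protein of macrophages and Il1r2 the decoy receptor of interleukin 1.

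T-cell identity genes had 16 of 18 members higher and 0 lower in CT-26 and a median of 1.46 (above all 10000 random lists). The naive and central memory list had 14 of 20 members higher and 0 lower, with a median of 1.34 (above all 10000 random lists). Nsg2 reached 3.16, Dapl1 3.11, Ccr9 3.08 and Tcf7 2.67. TCR variable segments had 17 of 125 members higher and 0 lower and a median of 1.73 (above all 10000 random lists; 1.56 with zeros at their bound). Class I antigen presentation had 1 of 12 members higher and 0 lower (median 0.43, percentile 80.3), and ribosomal protein genes 3 of 75 members higher and 0 lower (median 0.32, percentile 84.0).

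Effector genes were lower in CT-26 CTRL. The effector and memory differentiation list had 1 of 25 members higher and 17 lower and a median of -1.65 (below all 10000 random lists), with Anxa1 at -5.03 and Cd44 at -2.69. Myeloid cells express both genes, and the neutrophil and monocyte lists fell further in CT-26, to medians of -6.28 and -5.41. Cytotoxic effector genes had 5 of 19 members higher and 9 lower and a median of -1.02 (percentile 0.05). Gzma was at -3.27 and Gzmb at -2.10, while Gzmm reached 2.96 and Gzmk 1.39. Ifng, at -0.69, did not pass the rule. NK cells express Gzma and Gzmb too, and the NK cell list fell beside them, with 0 of 18 members higher and 11 lower (median -5.44, below all 10000 random lists; -5.18 with zeros at their bound).

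TCR activation genes had 4 of 23 members higher and 10 lower in CT-26 (median -1.31, below all 10000 random lists), with Egr1, an early response gene, at -3.74 and Irf8 at -4.48. Inhibitory receptor genes had 1 of 20 members higher and 5 lower (median -0.74, percentile 1.23), Entpd1, the ectonucleotidase CD39, being at -3.17 and Pdcd1, which did not pass the rule, at 0.62. Interferon-stimulated genes had 2 of 29 members higher and 16 lower (median -1.15, below all 10000 random lists), with Oasl2 at -5.48 and Ifi44 at -4.66. Myeloid, dendritic and B cells express Irf8, Entpd1 or interferon-stimulated genes too, and their lists fell further in the same comparison, to medians of -5.41 (monocyte), -4.14 (dendritic cell) and -2.25 (B cell). Proliferation genes had 3 of 28 members higher and 6 lower (median -0.66, percentile 0.82), with Mki67 at -1.29. Chemokine receptor and integrin genes had 6 of 19 members higher and 4 lower (median -0.25, percentile 5.96), with Itgae at 3.66 and Ccr2 at -3.44. Glycolysis genes had 0 of 17 members higher and 4 lower (median -0.30, percentile 2.37), oxidative phosphorylation genes 0 of 23 members higher and 0 lower (median -0.30, percentile 0.7), heat shock genes 1 of 16 members higher and 3 lower (median -0.53, percentile 1.55) and mitochondrially encoded genes 0 of 30 members higher and 2 lower (median -0.15, percentile 29.0). The last of these medians turned positive under total scaling. Cells of other types express the proliferation, metabolic, heat shock and mitochondrially encoded genes too. The NK and plasma cell lists fell to -5.44 and -3.97 in the same comparison, so these medians cannot be read as the state of the CTRL T cells.

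Among markers of other cells in CT-26, neutrophil genes had 0 of 15 members higher and 15 lower (median -6.28, below all 10000 random lists), with the calcium-binding protein gene S100a8 at -6.79. Monocyte and macrophage genes had 0 of 21 members higher and 17 lower (median -5.41, below all 10000 random lists), with Cd14 at -7.03, and dendritic cell genes 1 of 12 members higher and 7 lower (median -4.14, below all 10000 random lists). B-cell genes had 0 of 20 members higher and 19 lower (median -2.25, below all 10000 random lists), with Igkc, the kappa constant region, at -3.98, and plasma cell genes 0 of 12 members higher and 9 lower (median -3.97, below all 10000 random lists), with Jchain at -6.68. CD4 and regulatory T-cell genes had 0 of 11 members higher and 6 lower (median -1.86, percentile 0.13), with Cd4 at -4.89 and Foxp3, the regulator of regulatory T cells, at -3.78. Gamma delta T cell genes had 0 of 7 members higher and 4 lower (median -2.27, percentile 2.29), platelet genes 0 of 14 members higher and 6 lower (median -2.67, percentile 0.04) and erythroid genes 0 of 17 members higher and 12 lower (median -3.26, below all 10000 random lists). Melanoma genes had 1 of 8 members higher and 0 lower (median -1.76, percentile 1.41; -2.33 with zeros at their bound) and epithelial genes 0 of 12 members higher and 1 lower (median -0.29, percentile 35.0; -1.30 with zeros at their bound). Endothelial and stromal genes had 0 of 8 members higher and 0 lower, with a median of 0.48 but a mean of -0.26 (percentile 66.9; -0.87 with zeros at their bound).

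**Figure D2:**
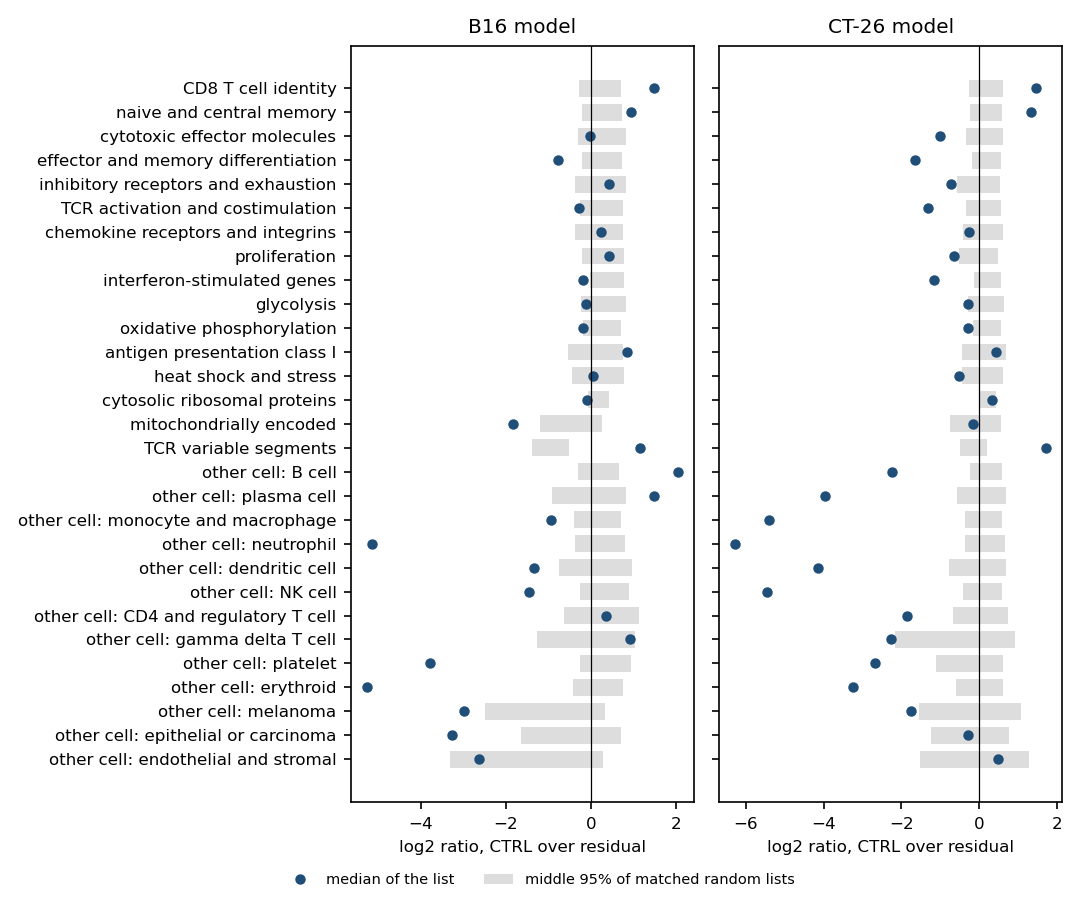
Median log2 ratio, CTRL over residual, of each of 29 gene lists in B16 (left) and CT-26 (right), as points, with grey bars for the middle 95% of medians of 10000 random lists matched on level. The B-cell list lies at 2.05 in B16 and -2.25 in CT-26, and the neutrophil list at -5.16 and -6.28.

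The models shared direction for T-cell, neutrophil and erythroid genes and parted for B-cell genes. Ngp (no reads in B16 CTRL, at least 4916-fold lower, and -7.20 in CT-26), Camp, Rhov, Ceacam10, Il1r2, S100a8, Sycp2, Wfdc21, Mcpt8 and Mrgpra2b were the 10 genes with the largest smaller ratio in a shared direction, leaving out predicted genes, pseudogenes and receptor segments, and every gene of these 10 was lower in CTRL. Gm44174, a predicted gene so left out and chosen after its values were seen, was higher in both, by 7.23 (5.56 to 13.35) and 7.08 (6.18 to 8.54). S100a8 was at -6.70 and -6.79, and Mcpt8, a protease of basophils, was at least 417-fold lower in B16, with no reads in CTRL, and at -6.48 in CT-26. Over 8765 genes at the level in both models, 763 were higher in both where independent lists would give 305, and 652 were lower in both where independent lists would give 143. The highest counts in 10000 random pairings of genes matched on level were 367 and 193. Another 111 genes were higher in B16 CTRL and lower in CT-26 CTRL, against 339 for independent lists, and 7 went the other way, against 129. Across 16786 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.470 and Spearman's rho 0.477. Of the 20 B-cell genes, 17 passed the rule in opposite directions, among them Cd79a (2.32 and -2.26) and Ms4a1, which encodes CD20 (2.49 and -2.24). With both models in 1 fit and the model as a block, which leaves 1 residual degree of freedom and takes any difference between models as error, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05. The lowest adjusted p was 0.184, that of Cd8a among others, and 2998 of 18749 genes had an unadjusted p under 0.05. DESeq2 with the same terms called 300 higher and 1499 lower, and edgeR without its low-count filter 167 and 820, so the number of calls rests on the tool and filter. The difference between models was not tested.

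**Figure D3:**
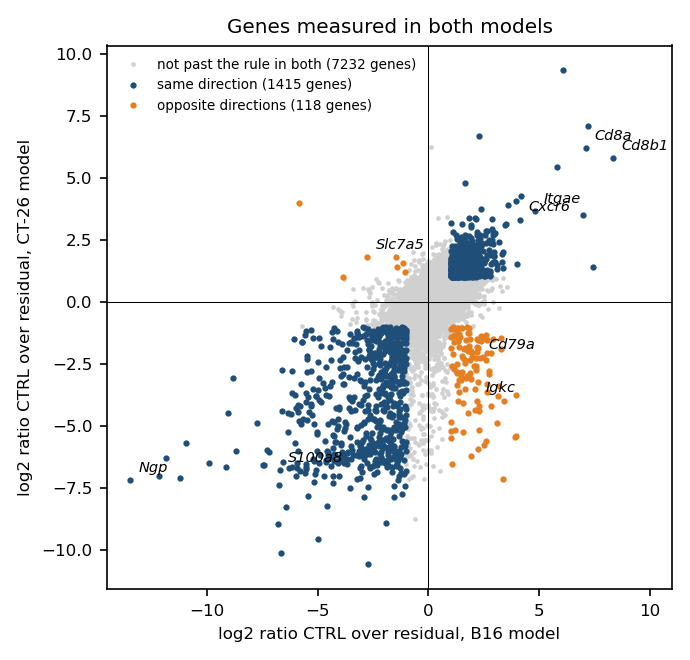
Log2 ratio, CTRL over residual, of each gene at the level in both models, with B16 on the x axis and CT-26 on the y axis, 1 point per gene. Blue points are the genes past the rule in the same direction and orange points the 118 past it in opposite directions, with Cd79a and Igkc among the latter. Genes with no reads in a library, such as Ngp in B16 CTRL, are drawn with the pseudocount of 1.

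TCR variable segments were spread over many genes in all 4 libraries. In B16, the effective number of Trav segments, which counts equally used segments, was 33.3 in the library labelled residual and 38.1 in CTRL, and that of Trbv segments 15.3 in both. In CT-26 the numbers were 31.0 and 30.5 for Trav, and 12.1 and 13.1 for Trbv. Depth may affect them, since the Trav reads were 778 in the library labelled residual and 3167 in CTRL in B16, and 3232 and 19127 in CT-26. The Trbv reads were 2008 and 11513 in B16, and 5919 and 35783 in CT-26. The T cells of the libraries labelled residual may be mostly not CD8+, so the segment shares may compare unlike T cells. Trbv12-1 held 1.79% of Trbv reads in the B16 library labelled residual (95% Wilson interval 1.30 to 2.47%) and 8.99% in CTRL (8.48 to 9.53%). Trbv1 held 11.8% and 6.59% in B16, and 13.5% and 8.34% in CT-26. Trbv13-2 was the most used Trbv segment of CT-26 CTRL, at 12.02%, beside 9.02% in the library labelled residual.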

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

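All tests of explanations in this part, and their bounds, were chosen after the results were seen.

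B-cell genes differed between models, with the median of their list higher in B16 by 4.30 log2 units (2.05 against -2.25), a difference that was not tested. Immunoglobulin V segments, which are not in that list, rose by a log2 ratio of 2.67 in B16 CTRL, as B cells in that library would give. The list holds Ighm, Ighd and Igkc, constant regions of the same transcripts, so the V segments are not separate support. MHC class II expression by CD8+ T cells could concern only Cd74 and the class II genes, and the list median without these was 2.32. With 18 of 20 members of the list higher, leaving out these few could hardly lower the median. The value shows only that the other members rose too. B cells in the B16 CTRL library may be the source of these transcripts, among them Cd79a at 6731 reads against 57203 and Igkc at 14892 reads against 117148. A selection for CD8+ cells would remove B cells. Whether B cells bound the multimer, or were left by the isolation, was not tested.

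Cd8a and Cd8b1 were low in both libraries labelled residual although the labels give CD8+ lymphocytes as their cell type. Dilution by RNA of cells that are not T cells would lower CD3 genes as much, but the smallest difference of a Cd8 gene from the CD3 median was 4.25 log2 units. Relative to CD3, the median of Cd4, Zbtb7b, Cd40lg and Foxp3 was lower in CTRL, the larger of the model values being -2.2 in B16, but there it came mostly from the CD3 rise of 1.78, with Foxp3 at 0.54, Zbtb7b at -0.24 and the CD4 and regulatory T-cell list at 0.36 (percentile 47.1). The T cells of the libraries labelled residual may be mostly not CD8+, with CD4+ cells a candidate source less directly seen in B16 than in CT-26, where Cd4 was at -4.89. Cd4 per Cd3e read was 0.4925 in the library labelled residual and 0.048 in CTRL in B16, and 0.594 and 0.00532 in CT-26. Residual may also mean all blood cells left after the isolation, which would make each ratio a comparison with mixed blood cells. This and a wrong label stay open, untested, while Cd8a per Cd3e read (0.0392 against 1.17 in B16 CTRL, and 0.0502 against 0.982 in CT-26 CTRL) goes against T cells that are CD8+ in both populations. The labels give PBMC as the source, although neutrophil and erythroid lists were higher in the libraries labelled residual than in CTRL.

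The median of the naive and central memory list was higher in both CTRL libraries. In B16, 10 of 20 members were higher and 1 lower, and in CT-26 14 were higher and 0 lower. Scaling alone is argued against, since a common factor would raise random lists of the same level as much, and the list median lay at percentile 99.8 of these in B16 and above all of them in CT-26. A larger share of T-cell RNA in CTRL may account for the list as a whole, since its median lay -0.0515 from that of the T-cell identity genes without Cd8a and Cd8b1 in CT-26 and -0.50 in B16. Single members went further, with 6 genes in CT-26 and 1 in B16 at least 1 log2 unit above the median of those genes. A difference in T-cell state stays open, untested, as does RNA of B cells in B16, where the B-cell list rose to 2.05, whereas in CT-26 it fell to -2.25.

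The plasma cell list also differed between models, by 5.45 log2 units in its median, a difference that was not tested. The list was mixed in B16, with 5 of 12 members higher and 1 lower, and a median of 1.48 but a mean of -0.78. Its member Iglc1 was at 2.72 in B16 and -2.80 in CT-26, whereas Igha was lower in CTRL in both models. By the authors' fold, Ighg2b (-3.74 in B16 and -5.36 in CT-26) and Jchain (-0.92 and -4.77) were lower in both as well. In B16, 7 of 12 members had a positive ratio, so the models differed in part of the list only. In all, 118 genes passed the rule of size in opposite directions in the models, which was not tested either.

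Olfactory receptor genes, for which no list was made, had reads for 1009 of 1407 genes in the B16 library labelled residual. Those with reads in a model were among the genes from which its random lists were drawn. The other libraries had reads for 223 (B16 CTRL), 102 (CT-26 residual) and 154 (CT-26 CTRL). Over all genes, the B16 library labelled residual had reads for 36955, against 24213 to 25243 in the others.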

How the results depend on the processing

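Scaling to totals without haemoglobin genes, all rescalings of the agreement counts, total scaling of single genes, the authors' fold for the correlations and the fits over both models were chosen after seeing the data. With no fold minimum, 6453 B16 genes were higher and 2836 lower, and 5740 CT-26 genes higher and 3774 lower; 4652 were higher in both models, 1997 lower in both and 2116 opposite. At a log2 ratio of at least 2, the counts were 409 and 551 in B16 and 208 and 974 in CT-26. These shifts follow from the limits themselves. Scaled to total reads, B16 counts moved to 5911 higher and 597 lower, and the shared counts to 1603 higher in both, 392 lower in both and 229 opposite. In B16 that scaling turned the medians of effector and memory differentiation (0.0707), TCR activation (0.56), interferon-stimulated (0.66) and ribosomal protein genes (0.74) positive, while their place among random lists stayed low, because total scaling shifts all genes by a nearly constant amount. With only members at a mean of at least 10 normalized counts, the gamma delta T cell list of B16 came to stand apart (1.36), while the heat shock (-0.38) and melanoma lists (-3.27) of CT-26 no longer did; the cause was not tested. Of the list medians under all alternatives, 283 kept their side and direction or had no call to lose, and 7 of these without a call changed sign. Some kept their side but shrank with the authors' fold. In B16 the neutrophil median went from -5.16 to -3.34, the melanoma median from -2.99 to -1.60 and the epithelial median from -3.27 to -1.76. Of the values of all named genes, called or not, 863 moved beyond counting error, 363 of them with the authors' fold. The other counts and correlations, 51 values, stayed within 1.5 times. With both models paired in 1 fit, edgeR called 0 genes in either direction at an adjusted p under 0.05, at 0.01 and with DESeq2 size factors, while without the low-count filter it called 167 higher and 820 lower, and DESeq2 300 and 1499; the cause was not tested. Tests within a model and leaving out a library were not run, since a model holds 1 library per group. Depth limits genes of few reads, such as Pdcd1 in the B16 library labelled residual.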

Other observations

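Several genes, chosen after their values were seen, rose in CTRL beyond the T-cell identity genes. In both models, 25 genes lay at least 1 log2 unit above the median of T-cell identity genes without Cd8a and Cd8b1. Beside the coreceptor genes and Itgae they include Kcna2, a potassium channel gene (5.80 in B16 and 5.46 in CT-26), Lcn4 (4.17 and 4.28), Ggt1, a gamma-glutamyltransferase gene (3.95 and 4.06), Ppic (3.60 and 3.89), Cxcr6 (4.14 and 3.32) and Art2b (3.49 and 3.14). Slc6a19, an amino acid transporter gene, had 20 reads against 2390 in B16, and in CT-26 it had no reads in the library labelled residual and was at least 166-fold higher in CTRL. Cd8a and Cd8b1 lay 5.69 and 6.88 above the reference median in B16, and 4.80 and 4.41 in CT-26. A larger share of CD8+ cells among the T cells of CTRL could thus raise genes of CD8+ cells beyond that median, which was not tested.

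Some interferon-stimulated genes were far higher in the B16 library labelled residual than others. Rsad2 had 103294 reads against 3835 in B16 CTRL (-5.52), Isg20 29429 reads against 2071 (-4.60) and Ube2l6 101479 reads against 6092 (-4.83). Ifit1 was at -0.93 and Ifit3 at 0.48, neither past the rule. Neutrophil (median -5.16), erythroid (-5.27) and platelet (-3.80) lists were far higher in the same library. In CT-26, Rsad2 was at -4.02, Isg20 at -2.64 and Ube2l6 at -4.04.

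Switched immunoglobulin genes, and Jchain, which encodes the joining chain, were abundant in the CT-26 library labelled residual. Igha had 25808 reads against 647 in CTRL, Ighg1 22049 reads against 590 and Jchain 10491 reads against 171. In B16, Igha had 1410 reads against 194, and Ighg1 25 reads against 0.

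The authors' deposited table gave p-values under 0.05, not adjusted, for 914 B16 genes and 1199 CT-26 genes, where 1926 and 1398 would be under that value for evenly spread p-values. Those 2 numbers count all genes with a p, 38516 in B16 and 27960 in CT-26, among them many genes of few reads. With 1 library per group, this comparison cannot show whether there are more or fewer differences than by chance. Of 70 B16 genes with a log2 ratio of at least 6 in size, computed with the pseudocount of 1, 28 had a p of 0.05 or more in the authors' deposited table, against 0 of 237 in CT-26. In the authors' deposited table for B16, Cd8b1 has a log2 fold of 1.94 (p = 0.278) and Ngp -0.92 (p = 0.556). From the normalized counts, the log2 ratio of Cd8b1 is 8.32, and Ngp, with no reads in CTRL, is at least 4916-fold lower.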
